A study of Drosophila melanogaster with 18 samples.

How the data were processed

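Total RNA from hand-dissected wing imaginal discs was read in 18 libraries, 6 for each of 3 groups: control clones on day 5, wts149 clones on day 5 and wts149 clones on day 9. Groups, numbers and letters were taken from the sample titles. The values are read counts per gene as deposited, which the authors made with HTSeq per the labels, and they were whole numbers with no normalization. The HTSeq version, the aligner, the genome build, the annotation release and the use of strand are not given in the sources used here. The table held 17373 genes by symbol, and genes at 0 in every library were kept in it.

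The labels give each group the numbers 1 to 3, each with a letter a or b, and do not say what the letters or the numbers are. The a and b libraries of a number were summed into 1 replicate, so that a and b never count as 2 samples, and n = 3 per group. Counts of a against b were compared by chi-square over genes with at least 10 counts. Chi-square over its degrees of freedom was 0.994 to 1.06 over the 9 pairs, against 11.1 to 58.9 between replicates of a group. Of the 9 pairs, 2 departed from counting noise (control replicate 1, ratio 1.06, p = 8.52e-05, and wts day 5 replicate 3, ratio 1.04, p = 0.0129, chi-square tests). The correlation of log2 CPM was 0.996 to 0.998 between a and b and 0.972 to 0.994 between replicates. Same-numbered replicates of different groups were not treated as pairs, since their deviations from the group means correlated at -0.167 to 0.244 and 3 of 9 correlated best with their own number.

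Depth was 5611674 to 11193858 counts per library and 14201662 to 22263073 per summed replicate. TMM factors ran from 0.972 to 1.04. Genes were kept by edgeR's filterByExpr with the group, which left 8585. All 3 groups were fitted together with edgeR 4.0.16 (quasi-likelihood F-test), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Means and SDs are CPM scaled with TMM. SEs of log2 fold changes come from the same fit, and log2 fold changes of genes near 0 counts depend on the prior count. For genes with 10 or fewer counts in a group, the ratio of summed counts is given with an exact 95% interval, and where a group had 0 counts the ratio was computed against a floor of 3 counts over the group. The fits ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

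The named genes followed a rule written before the data were examined. It took wts, then in each comparison the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM in a group and no overlap between the replicates of the groups. It also took up to 4 members with the smallest adjusted p from each list that had a call, and allowed any measured member of the Hippo and Yorkie lists. Genes outside the rule are said to be chosen after their values were seen. The 34 gene lists were also fixed before the data were examined, and were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over the lists), with camera at an estimated correlation, and with fry. Older symbols in the table were matched by hand to list members. Of 8585 tested genes, 8479 were placed on the Release 6 RefSeq annotation, which gave the positions printed, and the build that the authors used may differ.

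The overlap of the comparisons that share a group was set beside 20 simulations in which no group changed and every replicate was drawn anew from the shared group's mean. A first version kept the real shared replicates and drew the others around their mean, which left out the shared noise and gave mean correlations near 0, so it was replaced after the results were seen. The 6 replicates of each comparison were also divided in each of the 10 possible ways and fitted again. The tests were tested on simulated data with known changes before the real comparisons were made.

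Alternatives planned before the data were examined were DESeq2, RLE size factors, library size alone, every gene with a count, a stricter filter, limma-voom, the replicate number as a block, the 18 libraries as separate samples, the 18 libraries with duplicateCorrelation, the a or the b libraries alone, only the 2 groups compared, a fold threshold of log2 1, and leaving out each of the 9 replicates. For the overlap of the comparisons most of these were added after the data were seen, as were the scalings for the gene lists and the stricter filter, limma-voom and the fit of 2 groups for single named genes. No library and no column of counts was left out. The lesion of wts149 and the share of each disc that was mutant are not given in the sources used here, so the level of wts RNA does not check the genotype.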

Results

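RNA was sequenced from whole wing imaginal discs, the larval epithelial sacs that form the adult wing and thorax, dissected by hand from wandering Drosophila larvae. The discs carried clones made by Ubx-FLP recombinase on chromosome arm 3R in a Minute background, in which non-clonal cells grow slowly. Clones were either control clones on the FRT82B chromosome or clones of wts149, an allele of warts (wts), the Hippo pathway kinase that restrains the growth activator Yorkie. The samples formed 3 groups, control discs on day 5, wts discs on day 5 and wts discs on day 9. Each group had 3 numbered replicates and each replicate 2 libraries, a and b. The 18 libraries held 5611674 to 11193858 counts, and the 9 replicates, each the sum of its libraries, 14201662 to 22263073. Control replicates ran from 18063124 to 22263073 counts, wts day 5 replicates from 14201662 to 19762758 and wts day 9 replicates from 19297558 to 20899989. Intervals and floors on low counts given here cover counting error only. The labels do not say what a replicate is, so the p-values measure only the spread between these samples. Chi-square over its degrees of freedom was 11.1 to 58.9 between replicates of a group, against 0.994 to 1.06 between a and b libraries. This argues against replicates that differ by counting noise alone, but whether they are separate sets of larvae is not given. No control discs of day 9 were among the samples analysed here, so in the comparison of wts day 9 with control the age and the genotype change together. The labels give the controls as day 5, while their description text reads d5.d6.

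The first comparison asked which genes differ between wts and control discs that the labels both give as day 5. With the description text of the controls at d5.d6, an equal age is not established. The wts transcript itself (3R, 30789625 to 30806619) rose from 101 ± 5.38 CPM (counts scaled to a common library size, mean ± SD, n = 3) to 202 ± 14.6, a log2 fold change of 1.01 ± 0.07 (SE; adjusted p = 3.84e-05). Feedback components of the Hippo pathway that Yorkie is known to activate rose with it, kibra from 88.1 ± 4.46 to 278 ± 7.41 CPM and expanded (ex) from 851 ± 65.8 to 2284 ± 176 CPM. The insulin-like peptide Ilp8, which discs secrete to delay metamorphosis when their growth is disturbed, rose from 0.822 ± 0.904 to 48.9 ± 3.34 CPM. Among the genes that fell were ImpE2 (-5.04 ± 0.79), which the steroid hormone ecdysone induces, the myoblast marker Ama (-1.02 ± 0.13) and the muscle actin gene Act87E (-1.27 ± 0.24). In all, 828 genes were higher and 762 lower of 8585 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 204 and 316 of these changed at least 2-fold.

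The 8 largest rises on day 5 were ppk13, CG33509, Ilp8, CR45923, CG43394, Lasp, CG9521 and CG7059. The sodium channel gene ppk13 (2L, 21086790 to 21088751) went from 5 counts in the summed controls to 2891 in wts discs, a ratio of 686 (95% counting interval 294 to 2114). Its neighbour CG33509 (2L, 21084605 to 21086506) went from 8 to 1347 counts, a ratio of 199.7 (101 to 464). CG43394 rose from 27.2 ± 1.37 to 363 ± 24.0 CPM. The muscle and junction gene Lasp passed at an adjusted p of 0.0416, and its call ended in 8 of the 9 fits that left out 1 replicate, all but the fit without control replicate 3 (adjusted p 0.0563 to 0.131). The 8 largest falls were Sgs3, Sgs7, CG17669, Lcp3, Spn100A, Blimp-1, CG42500 and Fbp1. Sgs3 and Sgs7 encode salivary gland glue proteins and Fbp1 a fat body receptor. Control values ran from 0.984 to 2581 CPM for Sgs3 and from 2.25 to 114 CPM for Fbp1, each highest in control replicate 3. They ran from 4.27 to 164 CPM for Spn100A, 2.19 to 89.2 for Lcp3 and 2.45 to 24.4 for CG42500. Blimp-1 stood at 110 and 105 CPM in control replicates 1 and 3. In control replicate 2 it was 0.578, close to the wts day 5 values of 0.104 to 0.492. The calls of Sgs3 and Sgs7 ended without wts day 5 replicate 1 or 3 (adjusted p 0.0632 to 0.0758). The call of Blimp-1 ended without each of the wts day 5 replicates in turn (0.0529 to 0.0858), and that of Fbp1 without control replicate 3, each wts day 5 replicate in turn or wts day 9 replicate 3 (0.0564 to 0.135). CG17669 went from 752 counts to 1, a ratio of 634 (113 to 25080).

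**Figure D1:**
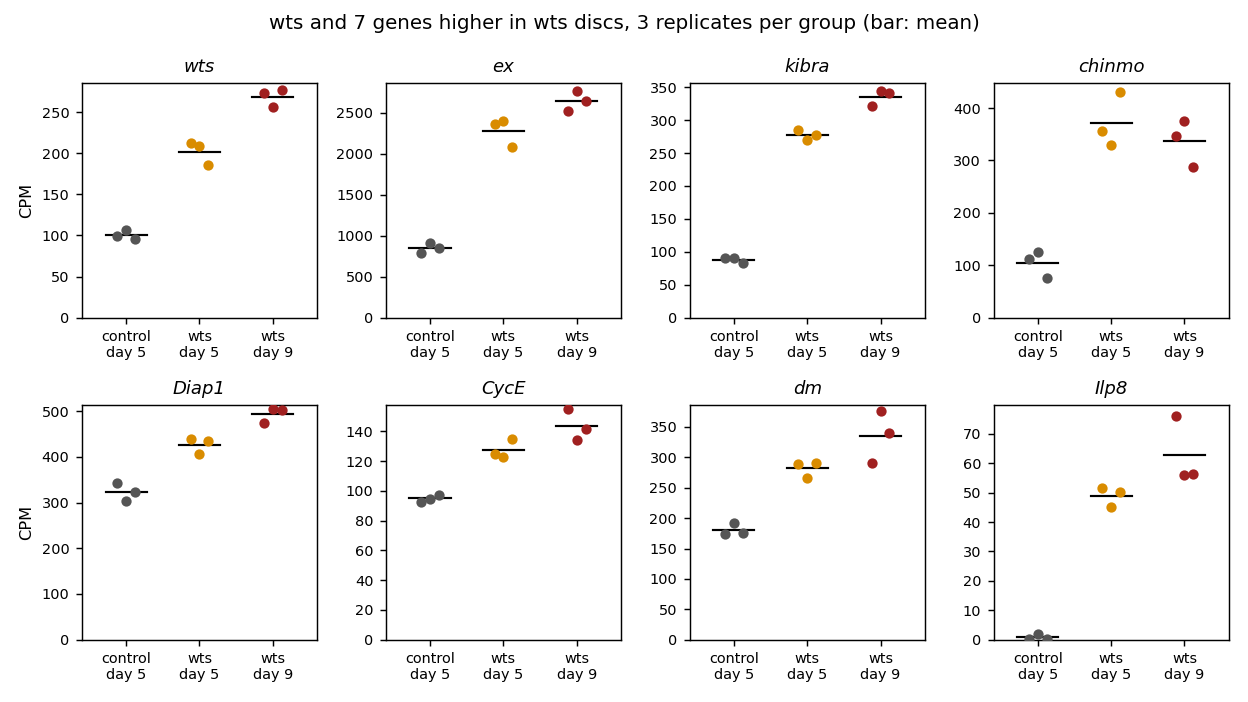
Scaled counts (CPM, linear axis from 0) of wts and 7 other genes in each replicate of control day 5, wts day 5 and wts day 9 discs; points are replicates and bars are means of 3. In each of the 8 genes every wts replicate lies above every control replicate.

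Of 21 measured Yorkie target genes, 10 rose, 2 fell and 9 did not pass on day 5, and 12 rose and 2 fell when adjusted over the list alone. The list was higher as a set (camera adjusted p = 3.89e-09), with an adjusted p of 0.0571 when the correlation between genes was estimated. The rises included the transcription factor chinmo (log2 1.83 ± 0.18), the cytokine genes os (1.03 ± 0.10) and upd3 (1.26 ± 0.19), the growth regulator dm (Myc; 0.65 ± 0.09), the G1/S cyclin CycE (0.42 ± 0.07) and the caspase inhibitor Diap1 (0.40 ± 0.07). The falls were the wing identity gene vg (-0.47 ± 0.09) and the Notch ligand Ser (-0.37 ± 0.11). The call of Ser ended without control replicate 1 or 3, each wts day 5 replicate in turn, or wts day 9 replicate 2 or 3 (adjusted p 0.0509 to 0.153). Among 19 Hippo pathway components, 2 rose (wts and the cadherin gene ft, 0.57 ± 0.12), 3 fell (Tgi, lft and hpo) and 14 did not pass, while adjusted over the list alone 3 rose and 3 fell. The call of hpo (-0.29 ± 0.08) ended without each of the 3 controls in turn, wts day 5 replicate 1 or 3, or wts day 9 replicate 3 (adjusted p 0.0514 to 0.129). yki itself stood at 88.6 ± 7.16 CPM in wts discs and 88.1 ± 5.40 in controls (adjusted p = 0.943).

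Of 21 tumour and stress transcription factors, 8 rose, none fell and 13 did not pass on day 5 (9 rose and 1 fell adjusted over the list alone), and 5 rose without wts day 5 replicate 3. Chinmo, the stress factor crc (0.57 ± 0.07), dm and CG13624 (REPTOR, 0.85 ± 0.14) led the list, whose camera adjusted p was 0.00499, against an adjusted p of 0.692 with an estimated correlation. Of 28 polarity and junction genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), including the septate junction genes Nrg (0.41 ± 0.07), cora (0.38 ± 0.07) and Cont (0.34 ± 0.06). Their camera adjusted p was 0.00477 and their adjusted p with an estimated correlation 0.692, and 5 rose without control replicate 1, 6 without wts day 5 replicate 1 and 6 without wts day 5 replicate 3. Of 87 ribosomal protein genes, 13 rose and none fell, over all genes and adjusted over the list alone alike, such as RpL15 (0.55 ± 0.09) and RpS3A (0.41 ± 0.08). Their camera adjusted p was 9.37e-05 and their adjusted p with an estimated correlation 0.771. The number that rose was 8, 6, 8 and 5 without control replicate 1, control replicate 3, wts day 5 replicate 1 and wts day 5 replicate 3. With library size alone as the scaling, 9 rose.

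Notch pathway targets were lower on day 5, with 10 of 19 down, none up and 9 not passing (11 down adjusted over the list alone). Examples are the wing margin gene ct (-0.92 ± 0.15), E(spl)mbeta-HLH (-0.77 ± 0.13) and E(spl)m2-BFM (-1.20 ± 0.21). The list had a camera adjusted p of 9.37e-05 and an adjusted p of 0.692 with an estimated correlation, and 6 fell without control replicate 1 or without wts day 5 replicate 3. Of 16 glycolysis genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone), among them Pglym78 (-0.47 ± 0.07), Tpi (-0.58 ± 0.11) and the hypoxia factor sima (-0.43 ± 0.07). Their camera adjusted p was 0.00218 and their adjusted p with an estimated correlation 0.692, and 3 fell without wts day 5 replicate 1 or 3. Of 14 wing pouch identity genes, 2 rose, 3 fell and 9 did not pass (3 and 4 adjusted over the list alone; camera adjusted p = 0.42), and 1 rose without wts day 5 replicate 1. The Dpp, Hedgehog and Wingless lists did not pass camera (adjusted p 0.221, 0.42 and 0.148), and of their single genes the Dpp target bi (omb; -1.06 ± 0.09), the Hedgehog receptor gene ptc (-0.71 ± 0.09) and the Wingless feedback gene nkd (-0.66 ± 0.08) fell, while the Dpp modulators magu (0.93 ± 0.08) and sog (0.95 ± 0.09) rose.

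Ecdysone response genes were lower on day 5, with 9 of 25 down, 1 up and 15 not passing (14 down and 2 up adjusted over the list alone). ImpE2 fell from 1789 ± 1182 to 54.3 ± 27.8 CPM, ImpE3 from 59.7 ± 43.1 to 3.08 ± 0.989 and Eip78C from 38.2 ± 29.3 to 0.701 ± 0.0768, while the nuclear receptor gene ftz-f1 rose (1.02 ± 0.17). The controls were not alike in these genes. The hormone-induced receptor gene Hr4, singled out after its values were seen, stood at 188 and 157 CPM in control replicates 1 and 3 and at 2.62 in control replicate 2, against 2.43 ± 0.301 in the wts day 5 replicates. The list's camera adjusted p was 0.00218 and its adjusted p with an estimated correlation 0.692, and 5 fell without control replicate 1 or without wts day 5 replicate 3. Of 26 heat shock and ER stress genes, 6 fell and 1 rose (16 and 1 adjusted over the list alone), with Hsp27 (-1.80 ± 0.21) and Hsp23 (-1.89 ± 0.35) down and crc up. Hsp68, chosen after its values were seen, ran from 6.24 to 2514 CPM among the controls and was highest in control replicate 1. The heat shock list had a camera adjusted p of 0.00218 and an adjusted p of 0.692 with an estimated correlation. Its number of falls was 2 without control replicate 1, 14 without control replicate 3, 2, 3 and 2 without wts day 5 replicates 1, 2 and 3, and 3 without wts day 9 replicate 3.

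Markers of other cell types moved on day 5 as well. Of 13 markers of the disc's myoblasts, the muscle precursors under the notum epithelium, 7 fell and none rose, the same counts as adjusted over the list alone, including Ama (-1.02 ± 0.13), zfh1 (-0.79 ± 0.11) and kirre (-0.87 ± 0.18). Their camera adjusted p was 0.000272 and their adjusted p with an estimated correlation 0.35, and 4 and 3 fell without control replicate 1 and wts day 5 replicate 3. Of 15 differentiated muscle markers, 8 fell and none rose (10 fell adjusted over the list alone), such as Act87E (-1.27 ± 0.24) and TpnC73F (-2.88 ± 0.57), whose call ended without wts day 5 replicate 3 (adjusted p 0.0521). Control replicate 2 was high in Mlc1, singled out after its values were seen, with 74.4 CPM against 12.8 and 11.5 in control replicates 1 and 3. The muscle list's camera adjusted p was 0.00126 and its adjusted p with an estimated correlation 0.692, and 4, 2 and 1 fell without control replicate 2, wts day 5 replicate 1 and wts day 5 replicate 3. Tracheal markers were split, with 4 of 13 up and 2 down (5 and 2 adjusted over the list alone), Osi15 (3.51 ± 0.31) and uif (0.73 ± 0.10) rising and dys (-1.23 ± 0.19) and btl (-0.89 ± 0.14) falling. The list's camera adjusted p was 0.0481, and its adjusted p with an estimated correlation was 0.692. That set call ended without control replicate 2, wts day 5 replicate 1 or wts day 5 replicate 2. Of 4 salivary gland markers, 2 fell, Sgs3 and Sgs7 (4 adjusted over the list alone), and this set call ended without control replicate 3. By camera the list's adjusted p was 0.0481, and its adjusted p with an estimated correlation was 0.692. More salivary markers passed the filter without control replicate 1, wts day 9 replicate 1, wts day 9 replicate 2 or wts day 9 replicate 3, and 7, 8, 7 and 7 of them fell. None fell by edgeR without wts day 5 replicate 1 or 3. Of 6 dosage compensation and sex genes, 1 rose, none fell and 5 did not pass on day 5 (camera adjusted p = 0.418). The gene that rose, roX2, stood at 12.9, 24.5 and 25.8 CPM in control replicates 1, 2 and 3. In wts day 5 replicates 1, 2 and 3 it stood at 43.4, 40.3 and 56.3 CPM. Whether the groups differ in the sex of the larvae was not tested.

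Of the 34 lists, 12 passed camera on day 5, 5 of them higher and 7 lower, and none passed with an estimated correlation (limma's camera, 2 at an unadjusted p under 0.05), while fry called 7. Of all 8585 genes, 3183 (37.1%) had no overlap between the 3 wts and the 3 control values, a separation that chance gives 10% of genes. With library size alone in place of TMM scaling, 644 genes were higher and 1066 lower, with the median log2 fold change of all genes at -0.053 in place of -0.002. The number of calls was 1004 without control replicate 1, 946 without wts day 5 replicate 1 and 739 without wts day 5 replicate 3.

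The second comparison set wts discs of day 9 against the day 5 controls and asked which differences the older discs showed. wts reached 269 ± 10.9 CPM (log2 1.42 ± 0.07, adjusted p = 4.32e-06), kibra 335 ± 12.5 (1.93 ± 0.06), ex 2649 ± 120 (1.64 ± 0.09) and Ilp8 62.8 ± 11.5 (6.19 ± 0.45). The basement membrane and integrin genes LanB1 (0.50 ± 0.06) and mys (0.56 ± 0.06) rose, and so did scarface (scaf, 2.11 ± 0.18), a target of the stress kinase JNK. The muscle myosin gene Mhc fell from 63.3 ± 19.5 to 1.82 ± 1.94 CPM. In all, 1312 genes were higher and 1231 lower of 8585, and 296 and 334 changed at least 2-fold.

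The largest rises on day 9 were ppk13 (2056 counts against 5 in controls, ratio 437, 187 to 1347), CG33509 (894 against 8, ratio 119, 60.0 to 276), Ilp8, topi, CG43394 (549 ± 56.7 CPM), CR45923, CG15546 (3.51 ± 1.60 to 54.8 ± 2.62 CPM) and CG9521 (2.20 ± 0.602 to 31.5 ± 9.95 CPM). The largest falls were Sgs3, Sgs7, CG17669, Mlc1, Lcp3, Lcp4, Tm2 and up, of which Mlc1, Tm2 and up encode muscle proteins and Lcp3 and Lcp4 larval cuticle proteins. CG17669 had no count in any wts day 9 library against 752 in the controls, so it was at least 236-fold lower, against a floor of 3 counts over the group. Mlc1 went from 2162 counts to 6, a ratio of 339 (156 to 925). The call of Lcp4 (66.5 ± 63.6 to 0.281 ± 0.220 CPM) ended without control replicate 2 or each of the 3 wts day 9 replicates in turn (adjusted p 0.0667 to 0.11).

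Of the 21 Yorkie targets, 13 rose, 2 fell and 6 did not pass on day 9, over all genes and adjusted over the list alone alike. The list passed both with the preset correlation (camera adjusted p = 1.16e-09) and with an estimated one (adjusted p = 0.0485). The rises included dm (0.90 ± 0.09), Diap1 (0.61 ± 0.07), CycE (0.60 ± 0.07), the glypican gene dally (0.53 ± 0.06), dlp (0.69 ± 0.10), crb (0.48 ± 0.09) and E2f1 (0.33 ± 0.07), and vg fell (-0.89 ± 0.09). Of the 19 Hippo components, 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0685), Rassf (0.62 ± 0.07) and ft (0.65 ± 0.12) among the rises and Tgi (-0.39 ± 0.08) among the falls. The number of rises was 3, 3, 3 and 4 without control replicate 1, control replicate 3, wts day 9 replicate 2 and wts day 9 replicate 3, and 4 rose with library size alone.

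Signalling lists that rose on day 9 included JNK and AP-1 targets, with 7 of 19 up and 2 down (7 and 2 adjusted over the list alone). As a set the list had a camera adjusted p of 0.00281, and an adjusted p with an estimated correlation of 0.482. Ilp8, scaf, the filamin gene cher (1.25 ± 0.11) and the growth factor gene Pvf1 (1.13 ± 0.19) rose, while the death gene rpr fell (-1.20 ± 0.23). Of 16 Dpp pathway genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with sog (1.18 ± 0.09) and the repressor brk (0.83 ± 0.11) up and bi (-1.48 ± 0.09) down. Camera gave the list an adjusted p of 0.0156, and with an estimated correlation an adjusted p of 0.482. Of 21 tumour and stress transcription factors, 10 rose and none fell (11 and 1 adjusted over the list alone), led by crc (0.80 ± 0.07), dm and chinmo (1.69 ± 0.18). The set's camera adjusted p was 0.000214, and its adjusted p with an estimated correlation was 0.482. EGFR and Ras targets had 10 of 18 up and 2 down (10 and 3 adjusted over the list alone), but the list did not pass camera (adjusted p = 0.099). Among the rises were the repressor genes ttk (0.74 ± 0.09) and aop (0.41 ± 0.06). The list member pnt, chosen here after its values were seen, was lower in wts day 9 replicates 1, 2 and 3 (49.1, 41.3 and 45.3 CPM). In control replicates 1, 2 and 3 it stood at 69.2, 72.6 and 67.4 CPM.

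Of 28 polarity and junction genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone), including the septate junction genes Cont (0.55 ± 0.06), pck (0.47 ± 0.07) and sinu (0.50 ± 0.07). The list's camera adjusted p was 0.000293, and its adjusted p with an estimated correlation was 0.482. The number of rises was 9 without control replicate 1 and 11 with library size alone. Of 21 matrix and basement membrane genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), such as the integrin subunit genes mys and mew (0.38 ± 0.05), and the set call ended without wts day 9 replicate 1. By camera the list's adjusted p was 0.0071, and its adjusted p with an estimated correlation was 0.482. Of 13 tracheal markers, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with Osi15 (4.15 ± 0.31), serp (0.79 ± 0.10) and Gasp (0.98 ± 0.16) up. The markers btl and dys, chosen here after their values were seen, went the other way. In replicates 1, 2 and 3, btl stood at 10.5, 8.44 and 10.1 CPM against 13.7, 14.0 and 14.2 in controls. In the same order dys stood at 14.0, 14.9 and 14.6 CPM against 22.4, 16.1 and 23.7. As a set the list had a camera adjusted p of 0.00183, and an adjusted p with an estimated correlation of 0.482. Of 14 haemocyte markers, 3 rose and none fell (2 rose adjusted over the list alone), with 8 up without control replicate 3 and 1 up without control replicate 1, wts day 9 replicate 1 or wts day 9 replicate 2. Camera gave the list an adjusted p of 0.0287, and with an estimated correlation an adjusted p of 0.588. The haemocyte marker with the lowest adjusted p was the ferritin gene Fer1HCH (1.33 ± 0.09), and the set call ended without control replicate 1, control replicate 2 or wts day 9 replicate 1. Fer1HCH was also higher in wts day 5 replicates 1, 2 and 3 (282, 250 and 291 CPM) than in the controls (137, 128 and 116 CPM). The haemocyte list on day 5 had 1 up and 2 down, with a median log2 fold change of -0.87 (camera adjusted p = 0.356).

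Of 23 ribosome biogenesis genes, 16 fell and none rose on day 9 (18 fell adjusted over the list alone), among them nop5 (-0.61 ± 0.11), Nop17l (-0.63 ± 0.12) and Surf6 (-0.48 ± 0.08). The set's camera adjusted p was 2.51e-05, and its adjusted p with an estimated correlation was 0.512. The number of falls was 8, 8 and 7 without control replicate 2, wts day 9 replicate 2 and wts day 9 replicate 3. Of 16 glycolysis genes, 9 fell and 2 rose, over all genes and adjusted over the list alone alike (camera adjusted p = 0.00183, adjusted p with an estimated correlation 0.482), including Pglym78 (-0.63 ± 0.07), Gapdh2 (-0.53 ± 0.08) and Pgk (-0.39 ± 0.06). Of 31 oxidative and xenobiotic stress genes, 11 fell and 2 rose, over all genes and adjusted over the list alone alike (camera adjusted p = 0.0377, adjusted p with an estimated correlation 0.588), with GstE8 (-1.74 ± 0.24) and Sod2 (-0.40 ± 0.06) down. Falls numbered 7, 7, 6 and 7 without control replicate 1, wts day 5 replicate 3, wts day 9 replicate 2 and wts day 9 replicate 3, and the set call ended without control replicate 1, control replicate 2, wts day 9 replicate 2 or wts day 9 replicate 3. Of 87 ribosomal protein genes, 3 rose and 3 fell, and none passed by edgeR adjusted over the list alone (camera adjusted p = 0.563). Without wts day 5 replicate 3, 5 rose and 1 fell. The rises numbered 1 without control replicate 1, control replicate 3, wts day 9 replicate 2 or wts day 9 replicate 3. The falls numbered 0 without control replicate 1, wts day 9 replicate 2 or wts day 9 replicate 3, and 1 without control replicate 2 or wts day 5 replicate 2.

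Notch pathway targets had 13 of 19 down and none up on day 9, over all genes and adjusted over the list alone alike (camera adjusted p = 8.84e-06, adjusted p with an estimated correlation 0.482), including dpn (-1.68 ± 0.17), E(spl)mgamma-HLH (-2.68 ± 0.29) and E(spl)m4-BFM (-2.29 ± 0.30), and 8 and 7 fell without wts day 9 replicates 1 and 3. Of 15 differentiated muscle markers, 12 fell and none rose (12 fell and 1 rose adjusted over the list alone), and Tm1, sls and Msp300 did not pass. The list's camera adjusted p was 1.75e-08, and its adjusted p with an estimated correlation was 0.482. Of 13 myoblast markers 2 rose, Mef2 (0.31 ± 0.06) and mbc (0.30 ± 0.07), and 1 fell, kirre (-0.83 ± 0.17), the same counts as adjusted over the list alone, while 3 fell without wts day 9 replicate 1. The median of the myoblast list was 0.04, its mean -0.04 and its test direction up (camera adjusted p = 0.917). The ecdysone list had 5 of 25 up and 2 down (5 and 2 adjusted over the list alone; camera adjusted p = 0.753), with Eip93F (2.33 ± 0.46) and ftz-f1 (0.82 ± 0.17) up. Its median log2 fold change was 0.08, its mean -0.38 and its test direction up. Without control replicate 2, the control with the lowest Hr4, 8 ecdysone genes were lower on day 9, and 1 was lower without wts day 9 replicate 2. Without control replicate 3, the control with the lowest Hsp68, 15 heat shock and ER stress genes were lower, against 3 higher and 3 lower with all replicates, and 1 was lower without control replicate 1, wts day 5 replicate 1 or 3, or each wts day 9 replicate in turn.

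Of the 34 lists, 13 passed camera on day 9, 8 higher and 5 lower, 1 passed with an estimated correlation (the Yorkie targets) and fry called 18. Library size alone gave 1069 genes higher and 1580 lower, with the median log2 fold change of all genes at -0.066 in place of -0.014. The number of calls was 1548 without wts day 9 replicate 2.

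**Figure D2:**
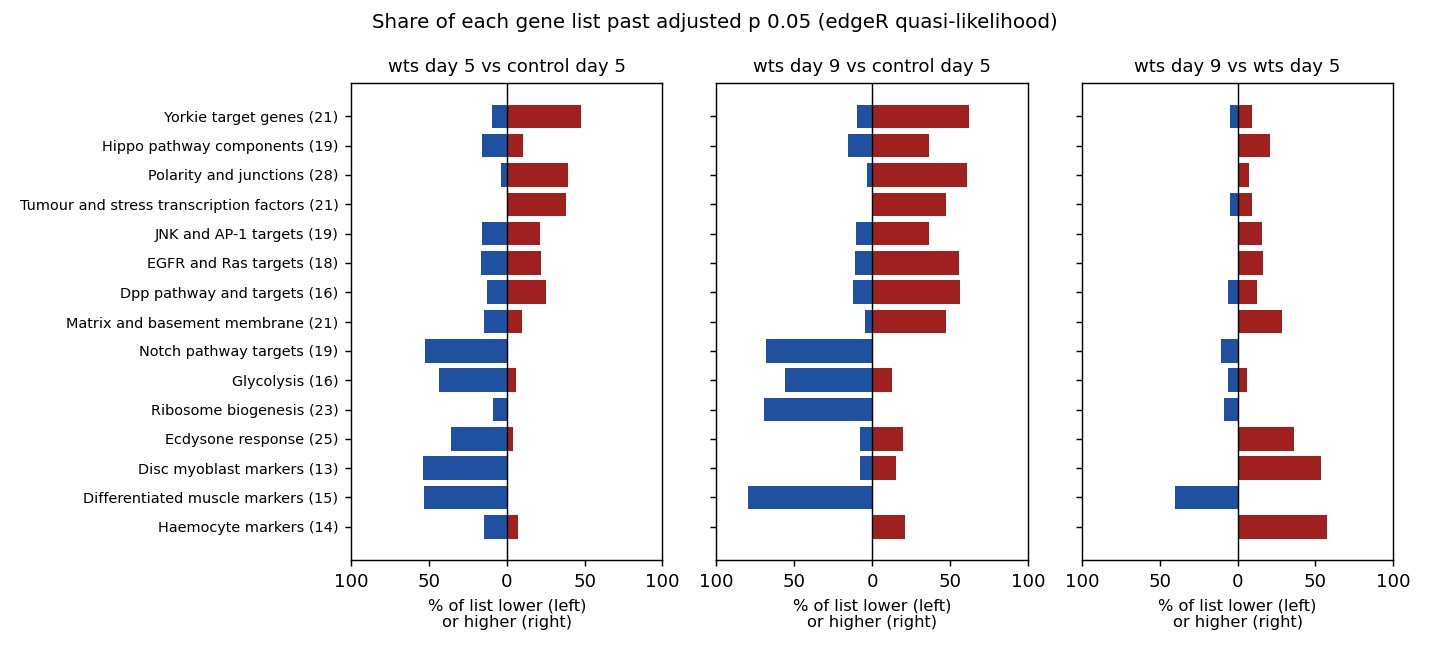
Percent of the measured members of 15 gene lists (number of members in parentheses) that were lower (left, blue) or higher (right, red) at an adjusted p under 0.05 in each of the 3 comparisons; the horizontal axes run from 0 to 100% each way. Yorkie targets had 10 of 21 members higher on day 5 and 13 on day 9, and Notch targets 10 and 13 of 19 lower.

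The calls of the 2 comparisons with control overlapped, 624 genes being higher on both days and 420 lower on both. Independent lists of these sizes would share 126.5 and 109.3 genes. The log2 fold changes correlated across 8585 genes at 0.657, against a mean of 0.515 in 20 simulations in which nothing changed and both comparisons shared the controls, so the correlation by itself says little. Their covariance was 0.468, against a simulated mean of 0.054. Genes are not independent replicates, the simulations drew each gene separately, and 3 controls are too few to split, so part of the excess may come from the shared controls. In opposite directions, 17 genes were lower on day 5 and higher on day 9, among them the insulin receptor gene InR and the chitinase gene Cht5, and 1, CG31262, was higher and then lower. These 3 genes were chosen after their values were seen. The shared calls numbered 686 without control replicate 1, 634 without wts day 5 replicate 1 and 592 without wts day 5 replicate 3.

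The third comparison, of wts day 9 with wts day 5 discs, held the genotype label fixed and asked what changed with age. The myoblast marker Ama rose (0.82 ± 0.13), and the muscle myosin gene Mhc fell (-3.93 ± 0.63). scaf rose from 85.0 ± 24.9 to 385 ± 31.4 CPM (2.18 ± 0.18, adjusted p = 0.000506) and the Wnt receptor gene drl from 416 ± 19.7 to 669 ± 34.8 CPM (0.68 ± 0.08). wts rose by a further log2 0.41 ± 0.07 (adjusted p = 0.0105). In all, 467 genes were higher and 249 lower of 8585, and 166 and 49 changed at least 2-fold.

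The largest rises with age were Spn100A, Blimp-1, Eip78C, St2, daw, Ef1alpha100E, ImpE3 and ImpE2, of which Blimp-1, Eip78C, ImpE3 and ImpE2 respond to ecdysone. Ef1alpha100E rose from 8.42 ± 3.54 to 108 ± 5.33 CPM, and its call ended without wts day 5 replicate 3 (adjusted p 0.0532). Eip78C rose from 0.701 ± 0.0768 to 14.5 ± 10.4 CPM and ImpE2 from 54.3 ± 27.8 to 608 ± 352, and the calls of Spn100A, Eip78C, St2, ImpE3 and ImpE2 ended without each of the 3 wts day 5 replicates in turn, wts day 9 replicate 1 or wts day 9 replicate 3 (adjusted p 0.0521 to 0.129). The call of daw ended without each wts day 5 replicate in turn or wts day 9 replicate 2 or 3 (0.0526 to 0.0799), and that of Blimp-1 in every left-out fit except the one without control replicate 2 (0.0515 to 0.166). The largest falls were CG16884 (96.2 ± 48.7 to 5.29 ± 3.07 CPM), Mhc (27.6 ± 14.6 to 1.82 ± 1.94), Nplp4, CG16885 (79.8 ± 38.7 to 6.16 ± 2.05), bt, Obp99a (49.9 ± 3.06 to 15.9 ± 5.39), CG42575 (127 ± 12.3 to 46.3 ± 3.17) and CG14566. The call of Nplp4 ended without wts day 5 replicate 2 or 3 or each wts day 9 replicate in turn (0.0579 to 0.0987), that of bt without wts day 9 replicate 2 or 3 (0.0513 and 0.0537), and that of CG14566 without each of the 6 wts replicates in turn (0.0511 to 0.11).

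Of 25 ecdysone response genes, 9 rose and none fell with age (14 rose adjusted over the list alone). By camera the list's adjusted p was 4.4e-07, and its adjusted p with an estimated correlation was 0.277. The number that rose was 4, 0 and 0 without wts day 5 replicates 1, 2 and 3, and 2, 4 and 1 without wts day 9 replicates 1, 2 and 3. Within wts day 9, replicate 2 was the lowest in Hr4, at 5.49 CPM against 62.4 and 31.2 in replicates 1 and 3. Of 47 cuticle protein genes, 10 rose and none fell (15 and 5 adjusted over the list alone), such as Cpr64Ac (4.23 ± 0.59) and Cpr78E (2.25 ± 0.35). As a set the list had a camera adjusted p of 0.0021, and an adjusted p with an estimated correlation of 0.311. The number that rose was 6, 4, 5 and 5 without wts day 5 replicates 2 and 3 and wts day 9 replicates 2 and 3, and the set call ended without wts day 5 replicate 1.

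**Figure D3:**
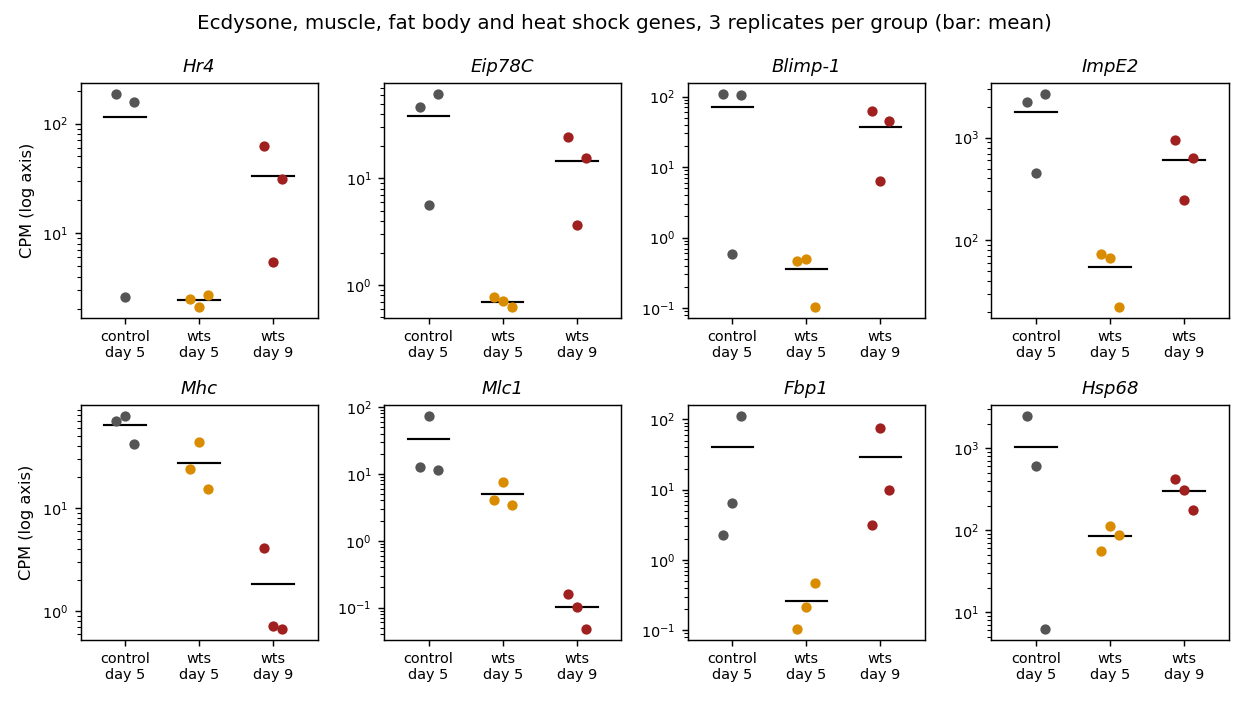
Scaled counts (CPM, log axis) of 4 ecdysone-responsive genes, 2 muscle genes, the fat body gene Fbp1 and the heat shock gene Hsp68 in each replicate; points are replicates and bars are means of 3. Control replicate 2 lies at 2.62 CPM of Hr4 against 188 and 157 in the other controls, and Mlc1 is at most 0.160 CPM on wts day 9.

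Of 13 myoblast markers, 7 rose and none fell with age (8 rose adjusted over the list alone), including Ama (0.82 ± 0.13) and sns (0.67 ± 0.12), with 4, 2, 4 and 3 without wts day 5 replicates 2 and 3 and wts day 9 replicates 1 and 3. Camera gave the list an adjusted p of 4.4e-07, and with an estimated correlation an adjusted p of 0.193. Of 15 differentiated muscle markers, 6 fell and none rose (8 fell adjusted over the list alone). The set's camera adjusted p was 1.27e-07, and its adjusted p with an estimated correlation was 0.311. The number of falls was 10 without control replicate 2, 3, 2 and 2 without wts day 5 replicates 1, 2 and 3, and 1 without wts day 9 replicate 2 or 3. Of 14 haemocyte markers, 8 rose and none fell (10 rose adjusted over the list alone), Pxn from 8.10 ± 1.03 to 32.5 ± 8.17 CPM and Hml from 10.8 ± 2.01 to 34.1 ± 9.32 CPM. The list's camera adjusted p was 4.57e-07, and its adjusted p with an estimated correlation was 0.311. The number that rose was 2, 1 and 0 without wts day 5 replicates 1, 2 and 3, and 1, 1 and 2 without wts day 9 replicates 1, 2 and 3. The call of Pxn ended without wts day 5 replicate 3 (adjusted p 0.0716), and that of Hml without each wts day 5 replicate in turn or wts day 9 replicate 1 or 2 (0.0612 to 0.114).

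Of 12 fat body markers, none passed by edgeR with age (7 at an unadjusted p under 0.05), and 5 rose adjusted over the list alone, with a median log2 fold change of 2.06. Without control replicates 1 and 3 in turn, 1 and 2 rose. Camera gave the list an adjusted p of 0.0484, and with an estimated correlation an adjusted p of 0.535. The set call ended without control replicate 2, wts day 5 replicate 1, wts day 5 replicate 2 or wts day 9 replicate 2. In that last replicate Fbp1 stood at 75.4 CPM against 3.15 and 9.73 in wts day 9 replicates 1 and 3, and Rfabg at 79.5 against 1.87 and 9.40, both chosen after their values were seen. Of 13 tracheal markers, dys alone passed (0.71 ± 0.19), as it did adjusted over the list alone, and its call ended without control replicate 1, wts day 5 replicate 2 or 3, or each wts day 9 replicate in turn (adjusted p 0.0647 to 0.144), while 2 rose without control replicate 2. By camera the tracheal list's adjusted p was 0.0376, and its adjusted p with an estimated correlation was 0.412. That set call ended without wts day 5 replicate 3 or wts day 9 replicate 1.

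Of 21 matrix genes, 6 rose and none fell with age (12 rose adjusted over the list alone), including Timp (0.99 ± 0.13) and mys (0.37 ± 0.06), and 3 rose without wts day 5 replicate 3. By camera the list's adjusted p was 4.2e-06, and its adjusted p with an estimated correlation was 0.277. Of 19 Hippo components, 4 rose and none fell (7 adjusted over the list alone), namely wts, Rassf, Tgi and lft. As a set the list had a camera adjusted p of 0.00101, and an adjusted p with an estimated correlation of 0.277. The number that rose was 1 and 1 without wts day 5 replicates 2 and 3, and 2, 1 and 1 without wts day 9 replicates 1, 2 and 3. The call of wts held in each fit that left out 1 replicate. JNK and AP-1 targets had 3 of 19 up and none down (4 up adjusted over the list alone), with 5 up without control replicate 2 and 1 up without wts day 5 replicate 2 or 3. Camera gave the list an adjusted p of 0.000506, and with an estimated correlation an adjusted p of 0.311. Among 21 Yorkie targets, 2 rose, 1 fell and 18 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.11). None of these rises was called by edgeR without each wts day 5 replicate in turn or wts day 9 replicate 2 or 3, and the fall was not called without wts day 5 replicate 2 or 3 or wts day 9 replicate 2 or 3. The difference of kibra between the ages (0.27 ± 0.06) was lost without each wts day 5 replicate in turn or wts day 9 replicate 2 or 3 (adjusted p 0.0504 to 0.0885). Ribosomal protein genes had 5 of 87 down and none up (1 down adjusted over the list alone), with 2, 3 and 1 down without control replicate 1, wts day 5 replicate 1 and wts day 9 replicate 1, and 0 without wts day 5 replicate 2 or 3 or wts day 9 replicate 2 or 3. The set's camera adjusted p was 4.35e-05, and its adjusted p with an estimated correlation was 0.561. Ribosome biogenesis genes had 2 of 23 down (2 adjusted over the list alone), Surf6 and bor, whose calls ended without each of the 6 wts replicates in turn or control replicate 1 (adjusted p 0.0504 to 0.15). The list's camera adjusted p was 0.000191, and its adjusted p with an estimated correlation was 0.471.

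Between the ages, 19 of the 34 lists passed camera, 14 higher and 5 lower, none passed with an estimated correlation (limma's camera, 6 at an unadjusted p under 0.05), and fry called 10. The number of genes called was 467, 219 and 152 without wts day 5 replicates 1, 2 and 3, and 432, 247 and 212 without wts day 9 replicates 1, 2 and 3. DESeq2 called 1223.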

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

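The tests of the ecdysone genes (the limit of the scaling test included), the muscle genes, neighbouring genes and sequence linked to wts were chosen after the results were seen, and the divisions of the samples and the test of overlapping annotation before.

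In total counts, library a of wts day 5 replicate 2 lay far below the other 5 libraries of its group, at 5611674 counts against 8589988 to 9934661. Chance sets 1 library apart in this way in about 1 in 20 groups, and 3 groups were examined. Its partner library b held 8589988 counts, and the summed replicate entered the fit with 14201662.

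Between the days, 18 genes were called in opposite directions against control. All 18 passed the direct test of wts day 9 against wts day 5, but genes chosen for 2 opposite calls have a difference equal to the sum of both changes, so this adds no support. Of these, 17 were lower on day 5 and higher on day 9, such as InR (-0.37 and 0.24), mam (-0.27 and 0.26), Cht5 (-0.72 and 1.26) and Ef1alpha100E (-2.08 and 1.58). CG31262 went the other way (1.23 and -1.08). These 5 genes were chosen after their values were seen. The number was 7 with only the 2 groups compared, 12 with limma-voom, 13 with every gene with a count, 15 with the replicate block and 25 with DESeq2.

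Lower ecdysone response genes in wts discs on day 5 were examined first. Higher on wts day 9 than on wts day 5 were 9 ecdysone response genes. That number was 4, 0 and 0 without wts day 5 replicates 1, 2 and 3. It was 2, 4 and 1 without wts day 9 replicates 1, 2 and 3. These rises cannot decide on a lowering tied to the genotype and equal on both days. Without controls of day 9, a rise with age on top of such a lowering would look the same. Scaling between groups would move every gene by 1 log2 amount, and as the whole cause it is argued against by 16 of the 25 measured ecdysone response genes, which lay more than 2 SE from the list's common shift of -0.16 (12 below it and 4 above). This test was rewritten, since its first version, a count under other scalings, could not have come out lower, and its next, on the 9 falling genes alone, gave 8 of 9. Discs of one label collected at different stages stays open, since the spread of the list among the 3 controls (median SD of log2 CPM 0.305) lay at percentile 100 of 10000 lists matched on expression, whose median was 0.134. Developmental timing that differs between the genotypes is a biological explanation that these tests leave open. It may act together with stage differences among controls. The description text of the controls reads d5.d6, so the controls and the wts day 5 discs may also differ in age.

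Muscle structural genes lower in wts discs on day 9 were examined next. Fewer myoblasts in the discs is argued against as the whole cause, because 7 disc myoblast markers were higher on wts day 9 than on wts day 5 and none was lower (4, 2, 4 and 3 higher without wts day 5 replicates 2 and 3 and wts day 9 replicates 1 and 3). Varying carry-over of tissue that holds differentiated muscle stays open, with a mean pairwise correlation of within-group deviations of 0.666 against a median of -0.006 in matched lists, at percentile 100. Genes of 1 muscle program switched on together would correlate too, so this test may not separate carry-over from regulation. The most abundant genes of the list, Tm1 (876 CPM in controls and 895 on wts day 9) and Msp300 (569 and 971), which tissues other than muscle also express, did not fall, while Act57B went from 145 to 9.66 CPM.

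Large differences shared by both wts groups were examined last, in 104 genes with a 4-fold change on both days (37 higher and 67 lower, 103 placed). Genetic background that differs between the control and wts chromosomes could place changed genes side by side, and 12 neighbouring pairs were found against a median of 1 and a highest of 7 in 10000 random sets (permutation p = 1e-04, the smallest these sets can give). All 12 pairs moved in the same direction, but they include tandem gene clusters (Lcp2 and Lcp3, Sgs7 and Sgs3, CG9521 and CG9518), which shared regulation would also place together. For overlapping annotation the test cannot tell, with 3 of the 12 pairs overlapping (CG5568 and CG18586, natalisin and CR44176, CG7059 and CG13857). By the rule set before the data were examined, that is too many to argue against it and too few to argue for it. The other pairs, such as CG33509 and ppk13, do not overlap each other in the reference annotation. Overlap with genes outside the pairs was not part of the test. In the 3 overlapping pairs, overlapping annotation cannot be told apart from background or shared regulation, with the use of strand in counting not given. For sequence linked to wts, 2.5% of the 200 tested genes nearest to wts changed 4-fold on both days against 1.6% of the other 1870 on the arm (Fisher's exact test, p = 0.378), a test that was rewritten after its first version, on day 5 calls, had given 26% against 17.65% (Fisher's exact test, p = 0.00528). Both sets of genes lie on the arm of wts, where the clones were made. The comparison therefore cannot detect sequence that differs along the whole arm, and nothing is concluded from it.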

How the results depend on the processing

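Alternatives for the overlap other than DESeq2 and the fold threshold, the scalings for gene lists, and the stricter filter, limma-voom and the fit of 2 groups for single genes were added after the data were seen, the rest before. The rise of wts kept its direction and its call in every alternative run, with left-out ranges of 0.97 to 1.08 (day 5 against control), 1.38 to 1.47 (day 9 against control) and 0.36 to 0.45 (day 9 against day 5).

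In the order day 5 against control, day 9 against control and day 9 against day 5, entering the 18 libraries separately called 3660, 4239 and 2923 genes against 1590, 2543 and 716, because each RNA then counts as 2 samples if a and b share it, which the labels do not say. The overlap of the comparisons with control rose from 1044 to 2418. A fold threshold of log2 1 left 520, 630 and 215 genes and an overlap of 302, since it only removes calls. Between the ages DESeq2 called 1223 and duplicateCorrelation 1269, and the cause was not tested. On simulated data with known changes, in the same order, DESeq2 made 33 false calls of 194, 26 of 192 and 29 of 190. There edgeR made 9 of 160, 11 of 159 and 11 of 164. The replicate block called 1293, 2260 and 528 genes, with an overlap of 871.

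Camera at an estimated correlation called 0, 1 and 0 gene lists against 12, 13 and 19 with the preset one, and fry called 7, 18 and 10. Fry asks another question, whether a list's genes change when taken by themselves, while camera compares them with the other genes tested. A larger correlation widens the camera test. The apoptosis regulators lost their call between the ages (adjusted p 0.0408 to 0.277) at an estimated correlation of -0.002, below the preset 0.01. Their unadjusted camera p went from 0.0216 to 0.0489, and the adjusted p also depends on the p-values of the other lists. A larger correlation within their own list is therefore not the cause of this loss. Camera with an estimated correlation thus differs from the preset form in more than the correlation, and what else changed was not tested. The smaller number of lists called with it cannot be put down to correlation alone.

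Leaving out each of the 9 replicates gave 739 to 1680 genes on day 5, 1548 to 2674 on day 9 and 152 to 873 between the ages, an overlap of 592 to 1183, and 12 to 14, 12 to 15 and 17 to 22 lists. The lowest counts came without wts day 5 replicate 3 (739, 152 and 592) and without wts day 9 replicate 2 (1548). Fewer samples lower the power, but different replicates moved the counts by different amounts, and the cause of that was not tested. Counts of 1 to 3 genes that moved against the main direction of a list also changed by over 1.5 times in many of these fits, and no statement rests on them.

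Of the named genes called, 128, 139 and 82 in the same order, 45, 25 and 62 lost their call in at least 1 alternative, 38, 19 and 62 of them in a fit that left out 1 replicate. None reversed in any alternative run. Depth limits genes near 0 counts: CG17669 and the Sgs genes have ratios with wide counting intervals, and on simulated data edgeR recovered 47.3% to 54.5% of 1.5-fold changes.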

Other observations

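The gene families here were picked by symbol after the main results were seen, and so were their tests, while the divisions of the samples were planned.

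Subunits of the proteasome, the complex that degrades tagged proteins, were lower in wts discs. Of 32 subunits 11 fell on day 5, where 21 did not pass, and 29 fell on day 9 against control, with none higher. The falls included Rpn12 (-0.61 ± 0.09 on day 9), Prosbeta3 (-0.58 ± 0.10) and Prosalpha5 (-0.57 ± 0.07). On day 5 the family's camera adjusted p was 2.45e-05, with an adjusted p of 0.848 at an estimated correlation. Their camera adjusted p on day 9 was 9.47e-13, with an adjusted p of 0.343 at an estimated correlation, which was 0.749 for these genes. Subunits of the mitochondrial ATP synthase and cytochrome oxidase had 16 of 19 lower on day 9 against control, such as ATPsynG (-0.53 ± 0.07) and COX7A (-0.50 ± 0.10), and no subunit called on day 5 by edgeR. Between the ages 8 of the 19 fell (camera adjusted p = 2.16e-10, adjusted p with an estimated correlation 0.269). Mitochondrial ribosomal protein genes had 13 of 72 lower on day 9 against control, mRpL12 (-0.37 ± 0.06) among them, with a camera adjusted p of 0.0085 and an adjusted p of 0.497 at an estimated correlation.

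Laminin and integrin genes moved the other way. All 6 members of that family were higher on day 9 against control, LanA rising from 959 ± 30.6 to 1317 ± 111 CPM and mew from 245 ± 2.08 to 319 ± 6.55 CPM (camera adjusted p = 0.000211, adjusted p with an estimated correlation 0.343). Serpins, inhibitors of secreted proteases, had 5 of 13 higher and none lower on day 9, Spn77Ba rising from 124 ± 6.24 to 258 ± 24.0 CPM (camera adjusted p = 0.0284, adjusted p with an estimated correlation 0.343).

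The main axis of variation over the 9 replicates (42.9% of the variance) set the controls apart from all wts replicates, and the next (21.5%) set wts day 5 apart from wts day 9. That next axis also spread the controls, with replicates 1, 2 and 3 at -8.81, 10.8 and -19.4. Control replicate 3 thus lay among the wts day 9 replicates (-23.0, -17.9 and -20.2). Calls on day 5 against control and calls between the ages share the wts day 5 discs. In these, 145 genes were lower on day 5 and then higher with age, against 41.5 if independent, and 41 were higher and then lower, against 24. Genes higher in both numbered 60, against 45, and genes lower in both 21, against 22.1. The shared discs enter the comparisons with opposite signs, so their noise alone moves genes in opposite directions, and the values for independent lists leave this out. The log2 fold changes correlated across genes at -0.298, against a mean of -0.516 in 20 simulations in which nothing changed, with a covariance of -0.167 against -0.057. The correlation by itself is therefore no sign of a reversal with age, and how many of the 145 genes the shared discs account for was not separated.

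With 3 replicates against 3 there are 10 divisions of the samples, too few for a share under 0.05. Fitted on the 2 groups alone, the real division called 1283, 2233 and 1031 genes on day 5, on day 9 and between the ages, and 1 of 10 divisions, the real one, gave as many in each comparison. The highest of the others was 0 by edgeR, with 410, 347 and 532 genes at an unadjusted p under 0.05.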
